A study of Homo sapiens with 9 samples.

How the data were processed

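RNA was measured in 9 libraries of cells labelled NCI-H69, in 3 groups of 3 biological replicates (NC, si_CSNK2B and si_P300), 48 hours after transfection. Per the labels, the libraries were read as single-end 50 bp reads on a BGISEQ instrument. Per the submitters' processing notes in the labels, HISAT and Bowtie2 were used, without versions or roles, on genome build GRCh38.p13. The counting tool, the gene annotation, any filter and the strand setting are not stated. The deposited table holds 17529 genes with 36 columns of single libraries, which were used or checked, and 12 columns of group averages, which were not used here.

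Per the file headers, the read count columns are expected counts, estimated by the authors and not scaled between libraries, of which 24.7% to 39.4% per library are exactly whole as deposited. The FPKM columns are, per the file headers, length-scaled values made by the authors, and they were used in alternatives. The TPM columns are, per the file headers, values scaled by the authors to a common total, also used in alternatives, with 1 missing value. The normalized read count columns, a signal per gene, were deposited as the read count rounded up and scaled by 1 factor per library. This was checked on the values, of which 100% met it within 0.02 of a whole read, and the kind of factor is not stated.

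Expected counts were rounded and analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the groups with a minimum count of 10, which left 13129 tested genes. Library sizes were scaled by TMM, and 1 quasi-likelihood model was fitted to all 9 libraries with 3 contrasts: si_CSNK2B against NC, si_P300 against NC, and si_CSNK2B against si_P300. Tests were two-sided, and genes were called at an adjusted p (Benjamini-Hochberg, over all tested genes in a contrast) under 0.05. The SE of a log2 fold change was its size divided by the square root of F, and intervals are 95%. Normalised CPM were counts over effective library sizes, with a prior count of 2 for log2 values. With 3 replicates per group, the smallest two-sided exact permutation p is 0.1. Total counts were 13.1 to 18.3 M per library.

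The 32 gene lists, with 707 members of which 2 were found under another symbol, the comparisons, their tests and the rule for named genes were fixed before the data were examined. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with at least 3 tested members, and p-values were adjusted over 90 tests of 30 lists. The test was run again with an estimated correlation. Each list's members were counted over all tested genes and adjusted over the list alone. Named genes were CSNK2B and EP300, and in each comparison with NC the 12 largest changes each way among called genes. These had all 3 knockdown libraries on 1 side of all 3 NC libraries and a mean count of at least 50 in the higher group, and symbols of uncharacterised, antisense, small RNA and mitochondrial genes were left out. The rule also took 5 genes each way from the direct contrast, which gave none, and up to 4 members per list with the lowest p. Genes outside the rule are said to be chosen after their values were seen. Another 3 lists (aminoacyl-tRNA synthetases, endoplasmic reticulum chaperones and folding enzymes, and EGFR ligands and MAPK feedback genes) were chosen after the data were seen, so their counts and medians are given without a test. Marker lists of intestinal epithelium, lung epithelium, hepatocyte and breast luminal epithelium were compared with a level of 10 CPM.

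The overlap of both comparisons with NC was set against 50 simulated pairs of unchanged groups that share the controls. The pipeline was tested on simulated data with 200 changed genes of about 13000 tested in each comparison. At changes of 1.5, 2 and 4 times, it recovered 22.4%, 80.6% and 95.5% of 67, 67 and 66 changed genes in si_CSNK2B against NC (13000 genes). In si_P300 against NC it recovered 34.3%, 68.7% and 98.5% (12980 genes), and in the direct contrast 29.9%, 73.1% and 97.0% (12990 genes). Calls on unchanged genes made up 5.71%, 6.94% and 8.90% of calls. The simulation changed far fewer genes, equally many up and down, than the 34.0% and 28.25% called in si_CSNK2B and si_P300 against NC. The shares recovered and falsely called may therefore differ in those comparisons. Of 200 random lists, camera gave 7 an unadjusted p under 0.05. The simulated genes were drawn independently of each other, so this could not show how camera fares on lists with correlated members.

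Alternatives were DESeq2 1.42.0, limma-voom, RLE factors, library sizes alone, no filter, a stricter filter (at least 1 CPM in 3 libraries and a mean count of at least 50), only the 6 libraries compared, a replicate block and each library left out in turn. They also took in limma-trend on log2 FPKM and TPM with pseudocounts of 1 and 0.1, with and without a filter at 1, an adjusted p under 0.01, and a log2 fold change of at least 1. For lists, fry and an estimated correlation were added. Figures were drawn with python 3.11.15 and matplotlib 3.10.9.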

Results

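Gene expression was measured by RNA-seq 48 hours after siRNA transfection, in cells that the labels name NCI-H69, an established small cell lung cancer line. The identity of the cells stays open, since the neuroendocrine signature of small cell lung cancer was near 0 in all 9 libraries (median of 0.108 CPM in NC). Per the labels, 3 groups of 3 biological replicates received a negative control siRNA (NC), an siRNA against CSNK2B, the regulatory subunit of the protein kinase CK2 (si_CSNK2B), or an siRNA against P300, the histone acetyltransferase encoded by EP300 (si_P300). Total counts per library were 17.8, 17.7 and 18.3 M in NC replicates 1 to 3, 17.0, 13.1 and 14.5 M in si_CSNK2B replicates 1 to 3, and 17.5, 14.3 and 16.2 M in si_P300 replicates 1 to 3. A count of 0 allows up to 0.164 to 0.229 CPM by library, for counting error only. Across 13129 tested genes, log2 CPM correlated at 0.974 to 0.992 between libraries of 1 group, a correlation across genes, which are not independent replicates. Pairs of an si_CSNK2B and an si_P300 library correlated at 0.977 to 0.989, against 0.984 to 0.986 within si_CSNK2B and 0.974 to 0.986 within si_P300. Pairs with an NC library lay at 0.955 to 0.967 for si_CSNK2B and 0.963 to 0.972 for si_P300. On a principal component analysis of 1000 genes, the component holding 59.7% of the variance placed NC at -33.7 to -30.0 and the other 6 libraries at 5.65 to 22.8. On the component holding 10.8%, si_P300 replicate 1 lay at -22.7 and the other 8 libraries at -3.72 to 13.4. The MTRNR2L genes, near-identical nuclear copies of mitochondrial ribosomal RNA sequence, took 2.53% ± 0.51 of the counts in NC, 3.97% ± 0.986 in si_CSNK2B and 3.08% ± 0.371 in si_P300 (SD, n = 3). Levels are TMM-normalised read counts scaled to library size (CPM), as mean ± SD of 3 libraries. The log2 fold changes come from edgeR with their SE, unless stated otherwise.

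The targeted genes were read first, as a check of the labels. CSNK2B (gene ID 1460, GRCh38 chromosome 6, 31665236 to 31670343, plus strand) stood at 182 ± 12.8 CPM in NC, 152 ± 14.6 in si_CSNK2B and 156 ± 7.47 in si_P300. Per library these were 193, 168 and 185 CPM in NC, 168, 149 and 139 in si_CSNK2B, and 158, 148 and 163 in si_P300. In si_CSNK2B against NC the log2 fold change of CSNK2B was -0.26 ± 0.104, a difference of -16.5% with a 95% interval of -28.7% to -2.26%, which did not pass (edgeR adjusted p = 0.0732). In si_P300 it was -0.22 ± 0.104 (edgeR adjusted p = 0.137). EP300 (gene ID 2033, chromosome 22, 41091786 to 41180079, plus strand) stood at 45.2 ± 4.93 CPM in NC, 37.5 ± 4.42 in si_CSNK2B and 36.8 ± 3.67 in si_P300. Its libraries read 41.8, 50.8 and 43.0 CPM in NC, 32.4, 39.4 and 40.6 in si_CSNK2B, and 40.1, 32.9 and 37.3 in si_P300. In si_P300 against NC the log2 fold change of EP300 was -0.30 ± 0.127, a difference of -18.6% with a 95% interval of -32.8% to -1.32%, which did not pass (edgeR adjusted p = 0.101). In si_CSNK2B it was -0.27 ± 0.127 (edgeR adjusted p = 0.119). Two-sided exact permutation tests of each target in its own group gave p = 0.1, the smallest that 3 against 3 allows. The transcript levels therefore do not separate the labelled knockdowns from each other, and the groups are called by their labels throughout. Without si_CSNK2B replicate 1 the log2 fold change of CSNK2B was -0.34 and passed (edgeR adjusted p = 0.0347), and DESeq2 also passed it at -0.28 (adjusted p = 0.0420), within a range of 0.0347 to 0.273 over 13 alternatives. Only these 2 of the 13 passed, and with library sizes alone in place of TMM it was -0.14 (edgeR adjusted p = 0.273). EP300 ran from -0.365 to -0.153 over 13 alternatives by edgeR, DESeq2 or limma-trend, and 0 of them passed (adjusted p of 0.0622 to 0.372). GENCODE 29 places GPANK1, LY6G5B and AL662899.2 over parts of CSNK2B, and MIR1281, RNU6-375P and the antisense genes AL035658.1 and EP300-AS1 over parts of EP300, so both levels are uncertain to that extent.

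**Figure D1:**
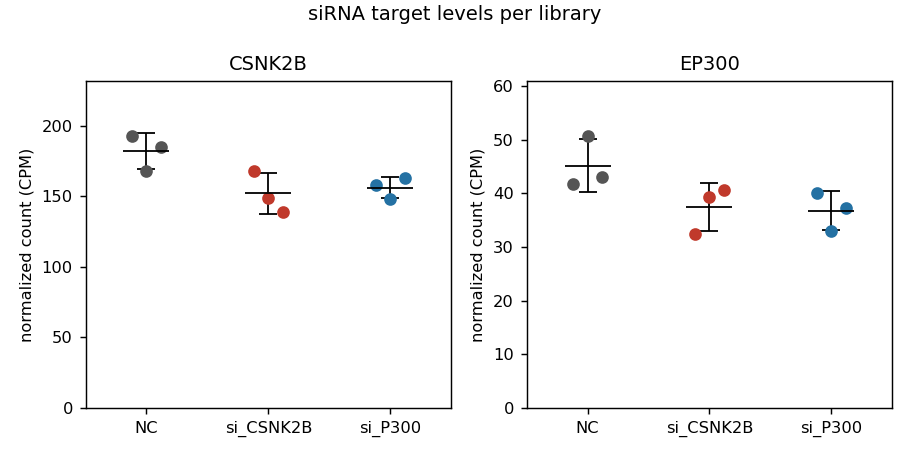
Normalised counts (CPM) of CSNK2B and EP300 in each library, with points for the 3 libraries of NC, si_CSNK2B and si_P300 and bars for the mean and SD. CSNK2B averaged 182, 152 and 156 CPM and EP300 45.2, 37.5 and 36.8 CPM, and neither target differed between si_CSNK2B and si_P300 by more than the spread between replicates.

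The comparison of si_CSNK2B with NC asks how the transcriptome differs where CSNK2B was targeted. EGR2, an immediate early transcription factor, fell from 26.3 ± 2.22 CPM in NC to 0.343 ± 0.222 in si_CSNK2B (log2 fold change -6.30 ± 0.851), and HSPA6, a strictly inducible heat shock protein, from 225 ± 49.9 to 3.24 ± 3.59 CPM (-6.18 ± 1.00). INHBE, an activin subunit gene induced by the transcription factor ATF4, fell from 99.6 ± 11.5 to 2.20 ± 1.15 CPM (-5.53 ± 0.273). HMOX1, which encodes the heme-degrading oxygenase, fell from 1404 ± 252 to 79.2 ± 11.9 CPM (-4.15 ± 0.388). FGF21, a stress-induced hormone gene (-5.01), TRIB3, a pseudokinase gene induced by ATF4 (-4.90), FOSB (-4.82), KLHDC7B (-4.62), HSPA1A (-4.01), EGR1 (-3.87), FOS (-3.83) and TMEM156 (-3.66) fell as well.

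Among the risers, APOBEC2, of the cytidine deaminase family, went from 1.08 ± 0.511 CPM in NC to 13.2 ± 4.52 in si_CSNK2B (log2 fold change 3.60 ± 0.403), and MSMB, a secreted protein of the prostate, from 1.91 ± 0.224 to 19.5 ± 9.38 CPM (3.35 ± 0.574). Pregnancy-specific glycoprotein genes, which the placental trophoblast expresses, made up PSG7 (3.28), PSG9 (2.89), PSG4 (2.86), PSG5 (2.64), PSG1 (2.57) and PSG11 of the 12 largest rises. PSG11 reached 72.0 ± 19.9 CPM from 12.7 ± 1.43. CXCL9 (2.96) and CXCL10 (2.54), chemokines induced by interferon, ESRRG (2.44), an orphan nuclear receptor, and ALDH1A3 (2.64), an enzyme of retinoic acid synthesis, completed the set. The PSG genes are near-identical copies of each other, as is HSPA1A of HSPA1B, so the split of reads between members is uncertain. The call of ALDH1A3 was lost without any 1 of the 3 NC libraries or without si_CSNK2B replicate 2 or 3 (edgeR adjusted p of 0.0647 to 0.0847). Without si_CSNK2B replicate 2 the log2 fold change was -6.89 for EGR2, -7.55 for HSPA6, -5.80 for FGF21, -5.69 for FOSB and 1.98 for PSG5, and without replicate 3 it was -4.26 for TMEM156, all of which still passed.

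In total 4462 genes passed in si_CSNK2B against NC, 2124 higher and 2338 lower (edgeR quasi-likelihood test, adjusted p under 0.05), of which 1078 differed by at least 1 on the log2 scale. The libraries of both groups did not overlap for 6957 of the 13129 tested genes, where chance gives 10%. With library sizes alone in place of TMM, 5021 genes passed and 66.0% of them were higher, against 47.6%, and the median of all genes moved from 0.0373 to 0.162 on the log2 scale. Without NC replicate 3 the count was 2928.

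Several of the gene lists moved as groups in si_CSNK2B. Of 27 tested targets of the unfolded protein response and ATF4, 22 fell and 3 rose (22 and 4 adjusted over the list alone), with a median log2 fold change of -1.90 and a lower list median in 3 of 3 libraries (camera adjusted p = 6.40e-29, and 0.160 with an estimated correlation). CTH, an enzyme of cysteine synthesis, fell 9.52-fold, and HERPUD1, a factor of endoplasmic reticulum-associated degradation, 6.74-fold. DNAJB9, a co-chaperone of that compartment, fell 4.76-fold, and SESN2, a stress-induced regulator of growth signalling, 3.31-fold. The 3 that rose, CALR, HSP90B1 and PDIA4, encode chaperones and a folding enzyme of the endoplasmic reticulum, and HSP90B1 and PDIA4 were named after their values were seen. Of 27 immediate early and CREB targets 23 fell and none rose, on both countings, with a median of -1.72 (camera adjusted p = 1.16e-12, and 0.646 with an estimated correlation). They included DUSP6, a phosphatase that restrains MAP kinase signalling (-2.90 ± 0.233), JUNB (-1.80 ± 0.221) and IER2 (-1.72 ± 0.191). Of 16 NF-kB targets 8 fell and 0 rose, on both countings, with a median of -0.54 (camera adjusted p = 0.00989, and 0.646 with an estimated correlation), among them CXCL8, a neutrophil chemokine (-1.81 ± 0.283), and NFKB1 (-0.96 ± 0.171). Of 14 tested BCL2 family genes 5 fell and 2 rose (5 and 3 adjusted over the list alone, median -0.17, camera adjusted p = 0.0322, and 0.676 with an estimated correlation). The falls took in the antiapoptotic BCL2L1 (-1.77 ± 0.107) and MCL1 (-1.57 ± 0.138) and the proapoptotic PMAIP1 (-1.57 ± 0.188) and BBC3 (-1.14 ± 0.175). Of 14 epithelial-mesenchymal genes 6 fell and 2 rose, on both countings (median -0.46, camera adjusted p = 0.0401, and 0.646 with an estimated correlation), the falls including the splicing regulator ESRP1 (-1.22 ± 0.110) and the tight junction gene CLDN7 (-0.77), both epithelial.

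Groups that rose in si_CSNK2B were led by the interferon response, with 17 of 29 tested members higher and 2 lower (18 and 3 adjusted over the list alone) and a median log2 fold change of 0.68 (camera adjusted p = 1.01e-04, and 0.692 with an estimated correlation). IFI44 rose 3.40-fold, and BST2, which tethers budding viruses, 1.94-fold. Of 38 oxidative phosphorylation genes 15 rose and 0 fell, on both countings (median 0.24, camera adjusted p = 1.67e-04, and 0.692 with an estimated correlation), including ATP5MC1 (1.11 ± 0.193), an ATP synthase subunit, and NDUFB3 (0.94 ± 0.153), of respiratory complex I. Of 30 genes of G2/M and mitosis 11 rose and 0 fell, on both countings (median 0.42, camera adjusted p = 0.00227, and 0.719 with an estimated correlation), including the mitotic kinesin KIF20A (1.33 ± 0.191) and the checkpoint kinase BUB1 (0.93 ± 0.152). For each of the 8 lists that passed in si_CSNK2B, the list median lay on the side of its change from the NC mean in 3 of 3 libraries. The lists were picked by their test on these same libraries, so this is not separate support. The BCL2 family median of si_CSNK2B replicate 3 (-0.059) lay within the range of NC (-0.0729 to 0.049). Without si_CSNK2B replicate 1 the calls of G2/M and mitosis, the BCL2 family and the epithelial-mesenchymal genes were lost (camera adjusted p = 0.0681, 0.0601 and 0.0939), within ranges of the adjusted p over 10 alternatives, 9 by camera and 1 by fry, of 9.99e-07 to 0.719, 0.0114 to 0.676 and 0.0114 to 0.646.

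Other lists did not pass in si_CSNK2B against NC. Of the 4 CK2 subunit genes 3 fell (4 adjusted over the list alone, camera adjusted p = 0.129), with CSNK2A2, a catalytic subunit, at -0.71 ± 0.142. Of 12 lysine acetyltransferases 3 fell and 1 rose (4 and 1 adjusted over the list alone, camera adjusted p = 0.240), with CREBBP, the paralog of EP300, at -0.84 ± 0.114 and KAT2A at 0.72 ± 0.0987. The histone acetylation readers and deacetylases had 7 lower and 2 higher of 20 (camera adjusted p = 0.247), with SIRT1 at -0.90 ± 0.114. The non-neuroendocrine signature of small cell lung cancer had 8 lower and 3 higher of 24 (camera adjusted p = 0.0901), with the receptor kinase gene EPHA2 falling from 584 ± 39.4 to 199 CPM and S100A10 rising from 1679 ± 38.1 to 3865 CPM. Of 25 autophagy and lysosome genes 7 fell and 2 rose (camera adjusted p = 0.149), with MAP1LC3B, an autophagosome marker, at -2.26 ± 0.107. Of 22 p53 targets 10 rose and 6 fell (camera adjusted p = 0.597), with TP53INP1 at 1.45 ± 0.168, and their median of 0.25 and mean of -0.03 differed in sign. Ribosomal protein genes, whose reads pseudogenes can share, had 13 lower and 1 higher of 56 (camera adjusted p = 0.113). DNA replication and E2F targets had 5 lower and 3 higher of 34 (0.755), with CDC6 at -1.02 ± 0.125. DNA repair genes had 5 lower and 4 higher of 35 (0.755), with CHEK2 at 0.66 ± 0.108. Of 25 genes of hypoxia and glycolysis 6 rose and 4 fell (camera adjusted p = 0.906, median 0.14, mean -0.09), with VEGFA at -1.74 ± 0.204 and the glucose transporter SLC2A1 at -1.42 ± 0.240. MHC class I genes had 2 higher and 3 lower of 18 (camera adjusted p = 0.577). Cholesterol biosynthesis had 6 higher and 3 lower of 24 (0.328). MYC family and targets had 4 higher and 3 lower of 26 (0.346), and drug transport and response 3 higher and 4 lower of 13 (0.980). Of 8 immune checkpoint ligands 3 were higher and 2 lower (camera adjusted p = 0.949, direction down against a median of 0.34), with PVR at -1.30 ± 0.0899. Of 18 Notch genes 2 were higher and 4 lower (0.755). Of 15 Wnt targets 3 were higher and 6 lower (0.952, median 0.05, mean -0.10), with DKK1 at 1.51 ± 0.185. Of 12 RNA interference genes 4 were higher and 2 lower (0.575). Adjusted over the list alone, these counts were the same except for the non-neuroendocrine signature (8 and 4), ribosomal proteins (12 lower), DNA replication (4 lower), DNA repair (3 higher and 4 lower) and drug transport (4 higher).

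Markers of other cell types and of neuroendocrine identity were read in the same way. In NC the neuroendocrine signature of small cell lung cancer had a median of 0.108 CPM over its 20 measured members and the neuroendocrine transcription factors and markers one of 0.571 CPM, while the non-neuroendocrine signature stood at 91.6 CPM. Of 4 tested members of the neuroendocrine signature 0 passed in si_CSNK2B and 0 in si_P300 (camera adjusted p = 0.599 and 0.835), with SYP at 0.649 ± 0.160 CPM in NC. Of 11 neuroendocrine transcription factors and markers 4 rose and 2 fell in si_CSNK2B (5 and 3 adjusted over the list alone, camera adjusted p = 0.565) and 4 rose in si_P300 (camera adjusted p = 0.346), with SOX2 at 1.02 ± 0.207 and 1.05 ± 0.206. Fibroblast markers had 2 tested members, COL1A1 (17.7 ± 1.14 CPM in NC) and PDGFRA (39.4 ± 4.18 CPM), with no test of the list and 0 calls. Of 4 leukocyte markers 1 rose in each comparison (camera adjusted p = 0.346 and 0.511), which was LYZ (2370 ± 108 CPM in NC, 0.61 ± 0.140 and 0.63 ± 0.140), while PTPRC, the pan-leukocyte marker, stood at 0.531 ± 0.159 CPM. Of 9 squamous and luminal epithelial markers 1 rose in each (camera adjusted p = 0.407 and 0.461), the mucin gene MUC1 (0.48 ± 0.117 and 0.44 ± 0.117), whose call in si_P300 was lost without NC replicate 2 or 3 (edgeR adjusted p = 0.0870 and 0.0655, within 0.00188 to 0.0870 over 13 alternatives). The counts for these marker lists were the same adjusted over the list alone, except as given. None of the 15 mitochondrially encoded genes had a value in the table.

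The comparison of si_P300 with NC asks the same of the cells in which P300 was targeted. KLHDC7B fell from 11.4 ± 3.07 CPM in NC to 0.407 ± 0.264 in si_P300 (log2 fold change -4.84 ± 0.431), INHBE from 99.6 ± 11.5 to 6.10 ± 1.46 CPM (-4.02 ± 0.241), TRIB3 from 30.7 ± 4.68 to 1.92 ± 1.11 CPM (-3.97 ± 0.299) and NUPR1, a stress-induced nuclear protein, from 111 ± 19.0 to 12.6 ± 2.77 CPM (-3.14 ± 0.197). HSPA6 (-4.40), the extracellular matrix gene ECM2 (-4.14), FOSB (-3.51), the stromelysin gene MMP10 (-3.37), FGF21 (-3.34), the sodium channel gene SCN4A (-3.22), EGR2 (-3.20) and the keratin gene KRT16 (-3.13) fell as well. Rises were led by FN1, which encodes fibronectin, from 0.176 ± 0.116 to 3.83 ± 3.17 CPM (4.39 ± 1.19), and by PSG7 (3.89), MSMB (3.11), PSG9 (3.00), PSG1 (2.92), APOBEC2 (2.86), PSG11 (2.78), PSG6 (2.74) and PSG4 (2.48), with the same uncertainty within the PSG family. The size and rank of the FN1 rise are uncertain, since NC held 9 counts of it in total and si_P300 replicate 2 stood at 0.413 CPM. UBD, a ubiquitin-like modifier induced by interferon, rose from 5.15 ± 0.350 to 38.7 ± 22.7 CPM (2.90 ± 0.515), and HSD3B1, a steroidogenic enzyme (2.81), and ALDH1A3 (2.63) completed the set.

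Libraries of si_P300 differed among themselves in immediate early and heat shock genes, a set chosen after the values were seen. In si_P300 replicate 1 FOS stood at 196 CPM, EGR1 at 233, EGR2 at 7.09, HSPA6 at 27.7 and HMOX1 at 328, against 16.7, 23.8, 0.689, 2.76 and 115 in replicate 2 and 18.7, 25.6, 0.489, 0.795 and 109 in replicate 3. Without replicate 1 the log2 fold change was -7.01 for HSPA6, -5.48 for EGR2, -5.13 for FOSB and -3.95 for SCN4A, and without replicate 2 it was 2.19 for MSMB, all of which still passed. The calls of FN1 and ALDH1A3 were lost without any 1 of the 3 NC libraries or without si_P300 replicate 3, and that of HSD3B1 without NC replicate 1 or 3 or si_P300 replicate 2 (edgeR adjusted p of 0.0530 to 0.130 over these). The log2 fold change was 3.74 for FN1 and 1.79 for ALDH1A3 without si_P300 replicate 3, and 1.84 for HSD3B1 without si_P300 replicate 2.

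In total 3709 genes passed in si_P300 against NC, 1783 higher and 1926 lower (edgeR quasi-likelihood test, adjusted p under 0.05), of which 755 differed by at least 1 on the log2 scale. The groups' libraries did not overlap for 46.5% of the tested genes, where chance gives 10%. With library sizes alone 4184 genes passed and 66.0% of them were higher, against 48.1%. Without NC replicate 1 the count was 2322 and without NC replicate 3 it was 2191.

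Of the 27 targets of the unfolded protein response and ATF4, 21 fell and 3 rose in si_P300 (22 and 4 adjusted over the list alone), with a median log2 fold change of -1.47 and a lower list median in 3 of 3 libraries (camera adjusted p = 1.71e-24, and 0.160 with an estimated correlation). DNAJB9 fell 5.64-fold, CTH 5.52-fold and HERPUD1 5.05-fold, and CALR, HSP90B1 and PDIA4 rose. Immediate early and CREB targets had 19 of 27 lower and 0 higher (23 and 1 adjusted over the list alone), with a median of -1.25 (camera adjusted p = 2.27e-10, and 0.672 with an estimated correlation), including DUSP6 (-2.14 ± 0.225) and FOSL1 (-2.04). Per library the list median was -0.65 in si_P300 replicate 1 and -1.55 and -1.63 in the other 2. Of 29 interferon response genes 16 rose and 0 fell (20 and 0 adjusted over the list alone), with a median of 0.79 (camera adjusted p = 4.57e-07, and 0.692 with an estimated correlation), including the antiviral OAS3 (0.94 ± 0.119) and IFI6 (1.05 ± 0.149). Per library the list median was 0.13 in si_P300 replicate 1 and 1.13 and 0.82 in the other 2. Of 30 genes of G2/M and mitosis 15 rose and 0 fell (18 and 0 adjusted over the list alone, median 0.41, camera adjusted p = 2.72e-05, and 0.692 with an estimated correlation), including BUB1 (0.99 ± 0.152) and KIF20A (1.22 ± 0.190). Of 38 oxidative phosphorylation genes 15 rose and 0 fell, on both countings (median 0.21, camera adjusted p = 9.69e-04, and 0.716 with an estimated correlation), including NDUFA4 (0.74 ± 0.124) and SDHA (0.41 ± 0.0888). The non-neuroendocrine signature had 10 lower and 1 higher of 24 (10 and 2 adjusted over the list alone, median -0.26, camera adjusted p = 0.0322, and 0.646 with an estimated correlation), with EPHA2 at -1.42 ± 0.153 and EMP1, an epithelial membrane protein, at -1.39 ± 0.147.

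The other 5 lists that passed in si_P300 each lost the call without at least 1 single library. MHC class I antigen presentation had 6 higher and 0 lower of 18 (7 and 0 adjusted over the list alone, median 0.34, camera adjusted p = 0.00955, and 0.692 with an estimated correlation), including the immunoproteasome subunit gene PSMB9 (0.77 ± 0.187). Its call was lost without si_P300 replicate 2 (camera adjusted p = 0.0658). NF-kB targets had 8 lower and 0 higher of 16, on both countings (median -0.36, camera adjusted p = 0.0322, and 0.692 with an estimated correlation), including CXCL1 (-0.76 ± 0.138), and the call was lost without NC replicate 1 or si_P300 replicate 2 (camera adjusted p = 0.0574 and 0.0567). DNA replication and E2F targets had 10 higher and 1 lower of 34 (11 and 1 adjusted over the list alone, median 0.26, camera adjusted p = 0.0226, and 0.841 with an estimated correlation), including the replication ligase LIG1 (0.74 ± 0.139). CDC6 was the 1 that fell (-0.80 ± 0.124). DNA repair genes had 7 higher and 1 lower of 35 (3 and 0 adjusted over the list alone, median 0.30, camera adjusted p = 0.0445, and 0.719 with an estimated correlation), including the mismatch repair gene MSH6 (0.68 ± 0.122). Ribosomal protein genes had 14 lower and 1 higher of 56, on both countings (median -0.18, camera adjusted p = 0.0187, and 0.845 with an estimated correlation), including RPS12 (-0.42 ± 0.0996). Without si_P300 replicate 1 these last 3 calls were lost (camera adjusted p = 0.181, 0.297 and 0.129), as were those of DNA replication without NC replicate 2 (0.0615), of DNA repair without NC replicate 1 or 3 (0.0743 and 0.0631) and of ribosomal proteins without NC replicate 3 (0.0757). Over 10 alternatives each, 9 by camera and 1 by fry, the adjusted p ran from 4.44e-04 to 0.692 for MHC class I, 0.00930 to 0.692 for NF-kB, 0.00774 to 0.841 for DNA replication, 0.00461 to 0.719 for DNA repair and 0.00121 to 0.845 for ribosomal proteins.

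Lists that did not pass in si_P300 included the BCL2 family, with 5 lower and 4 higher of 14 (camera adjusted p = 0.152), BCL2L1 at -1.46 ± 0.106 and MCL1 at -1.31 ± 0.137. Epithelial-mesenchymal genes had 5 lower and 2 higher of 14 (camera adjusted p = 0.113), with ESRP1 at -1.12 ± 0.110. CK2 subunits had 2 lower of 4 (3 adjusted over the list alone, camera adjusted p = 0.113), with CSNK2A2 at -0.60 ± 0.141. Lysine acetyltransferases had 2 lower and 1 higher of 12 (camera adjusted p = 0.343), with CREBBP at -0.83 ± 0.114. The readers and deacetylases had 7 lower and 1 higher of 20 (0.240). The p53 targets had 10 higher and 6 lower of 22 (11 and 6 adjusted over the list alone, camera adjusted p = 0.334), with FDXR at 1.00 ± 0.132. Autophagy and lysosome had 3 higher and 6 lower of 25 (4 and 6 adjusted over the list alone, 0.481), with MAP1LC3B at -2.13 ± 0.107, a median of 0.07 and a mean of -0.09. Cholesterol biosynthesis had 6 higher and 2 lower of 24 (camera adjusted p = 0.0852). Hypoxia and glycolysis had 8 higher and 3 lower of 25 (12 and 3 adjusted over the list alone, 0.247), with VEGFA at -1.60 ± 0.203. Immune checkpoint ligands had 3 higher and 2 lower of 8 (camera adjusted p = 0.952, direction down against a median of 0.38). Notch genes had 1 higher and 2 lower of 18 (0 and 2 adjusted over the list alone, 0.749). Wnt targets had 3 higher and 3 lower of 15 (4 higher and 5 lower adjusted over the list alone, 0.949, median 0.11, mean -0.05). MYC family and targets had 3 higher and 2 lower of 26 (0.346), drug transport and response 4 higher and 3 lower of 13 (0.755), and RNA interference genes 3 higher and 2 lower of 12 (4 and 2 adjusted over the list alone, 0.600). Where no second count is given, it was the same adjusted over the list alone. For each of the 11 lists that passed in si_P300, the list median lay on the side of its change from the NC mean in 3 of 3 libraries. These lists too were picked on the same libraries, so this is not separate support. The interferon median of si_P300 replicate 1 was 0.13, against 0.128 in NC replicate 3.

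**Figure D2:**
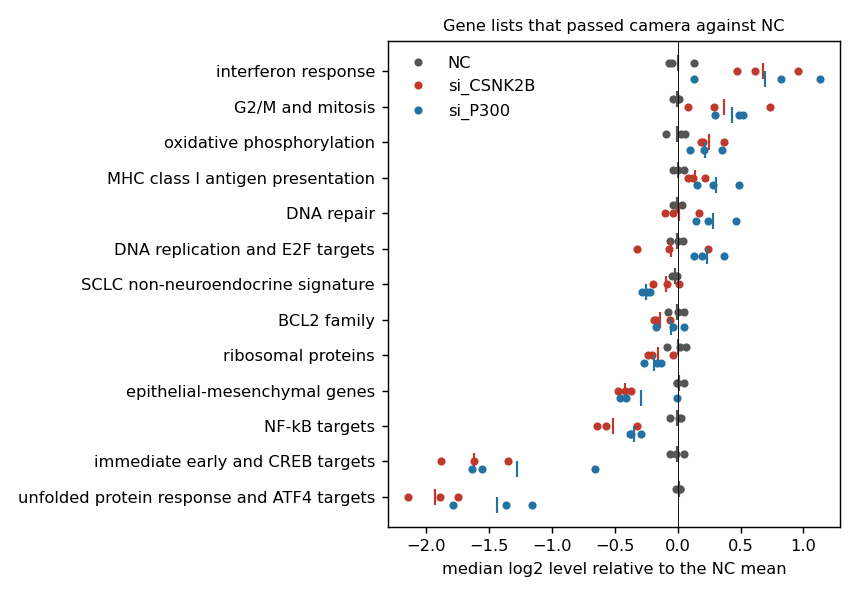
Median log2 level of each list's tested members relative to the NC mean, with a point per library and a bar for the mean of the 3 libraries, for every list that passed camera in at least 1 comparison with NC. The unfolded protein response and ATF4 list lay at -2.14 to -1.74 in si_CSNK2B and at -1.78 to -1.16 in si_P300.

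The direct contrast asks whether si_CSNK2B and si_P300 differ from each other. Among 13129 tested genes 0 passed (edgeR, lowest adjusted p = 0.149), 661 had an unadjusted p under 0.05, and the libraries did not overlap for 7.14% of genes, where chance gives 10%. Among other tools limma-voom called 0 genes. DESeq2 called 7, which were ADM2 (-1.42), INHBE (-1.49), SLC1A4 (-0.83), HSPB8 (-0.65), ERAP2 (-0.53) and SESN2 (-0.53), lower in si_CSNK2B, and RBBP4 (0.92), higher. On deposited TPM values with a pseudocount of 0.1 and no filter, limma-trend called 1, TEX46, with a mean count of 1.67 in si_CSNK2B and 0 in si_P300. The 95% interval of the difference lay within 1 of 0 on the log2 scale for 87.2% of the tested genes, so differences under that size were not excluded, nor larger ones for the rest. INHBE stood at -1.51 ± 0.289 in si_CSNK2B against si_P300, without passing (edgeR adjusted p = 0.588). The genes in this paragraph were chosen after their values were seen.

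Small shifts of whole lists passed camera in this contrast, with 0 members of any list passing over all genes. For every list that passed except autophagy and lysosome, the list medians of single libraries overlapped between the groups. Relative to the NC mean, DNA replication and E2F targets lay at 0.24, -0.07 and -0.32 in si_CSNK2B and at 0.37, 0.13 and 0.20 in si_P300. The unfolded protein response and ATF4 targets had a median log2 difference of -0.37 (8 lower adjusted over the list alone, camera adjusted p = 1.16e-12, and 0.479 with an estimated correlation), with SESN2 at -0.53 ± 0.111. DNA replication and E2F targets stood at -0.28 (3 lower adjusted over the list alone, camera adjusted p = 5.32e-18, and 0.646 with an estimated correlation), with MCM5, of the replicative helicase, at -0.53 ± 0.142. MHC class I antigen presentation stood at -0.26 (3 lower adjusted over the list alone, camera adjusted p = 1.78e-08, and 0.646 with an estimated correlation), with the peptide-trimming enzyme gene ERAP1 at -0.57 ± 0.117. DNA repair stood at -0.24 (camera adjusted p = 7.97e-07, and 0.667 with an estimated correlation). Immediate early and CREB targets stood at -0.46 (camera adjusted p = 1.22e-06, and 0.692 with an estimated correlation), hypoxia and glycolysis at -0.20 (0.00215, and 0.706), the BCL2 family at -0.15 (0.00989, and 0.646), autophagy and lysosome at -0.12 (0.0137, and 0.692) and oxidative phosphorylation at 0.05 (0.0401, and 0.845), with 0 members passing adjusted over the list alone. Without si_P300 replicate 1 the immediate early call was lost (camera adjusted p = 0.861), as were the BCL2 family (0.124), hypoxia and glycolysis (0.181) and oxidative phosphorylation (0.980), the last 2 with the direction turned. Without si_CSNK2B replicate 1 the calls of the BCL2 family (camera adjusted p = 0.103), autophagy (0.0875) and oxidative phosphorylation (0.867, direction turned) were lost. Those of hypoxia (camera adjusted p = 0.237) and autophagy (0.106) were lost without si_CSNK2B replicate 3, that of autophagy (0.352) without si_P300 replicate 2, and without si_P300 replicate 3 those of autophagy and oxidative phosphorylation (0.0525 each). The p53 targets and the non-neuroendocrine signature, which did not pass, had 1 lower and 1 higher member adjusted over the list alone, and the lowest camera adjusted p among lists that did not pass was 0.0719. Over 10 alternatives, 9 by camera and 1 by fry, the adjusted p of the 5 lists that lost a call ran from 3.78e-15 to 0.861, 0.00110 to 0.646, 1.15e-06 to 0.706, 2.90e-05 to 0.692 and 2.48e-04 to 0.980, in the order immediate early, BCL2, hypoxia, autophagy and oxidative phosphorylation.

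The overlap of both comparisons with NC was computed because both share the 3 NC libraries. Of the called genes 1447 rose in both and 1747 fell in both, 0 moved in opposite directions, and the 3194 shared calls made up 71.6% of those in si_CSNK2B and 86.1% of those in si_P300. Independent lists of these sizes would share 288.5 higher and 343 lower genes, and 50 simulations of unchanged groups against the same controls shared 0.02 genes on average and at most 1. Among the genes called in both, INHBE, TRIB3, EGR2, FOSB, HSPA6, FGF21 and KLHDC7B fell and APOBEC2, MSMB, ALDH1A3, PSG7, PSG9 and PSG11 rose. Across genes, which are not independent replicates, the log2 fold changes correlated at Pearson r = 0.914 and Spearman rho = 0.903, against 0.456 to 0.526 for Pearson r in the simulations. The covariance was 0.350 against a simulated mean of 0.0290, a difference of 0.321, which takes in anything that both knockdown groups share against the 1 set of NC libraries. With 3 control libraries the controls could not be split into groups of 2 or more, so part of the excess in shared calls may come from the shared controls. Over the 3194 shared calls the si_P300 change was a median of 0.909 times that of si_CSNK2B and was the smaller of the pair for 67.4%. On the first principal component si_P300 replicate 1 lay nearer to NC (5.65) than replicates 2 and 3 (15.98 and 14.96). The ratio was not computed without that library. Without NC replicate 1 the shared calls numbered 2066 and without NC replicate 3 they numbered 1942.

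**Figure D3:**
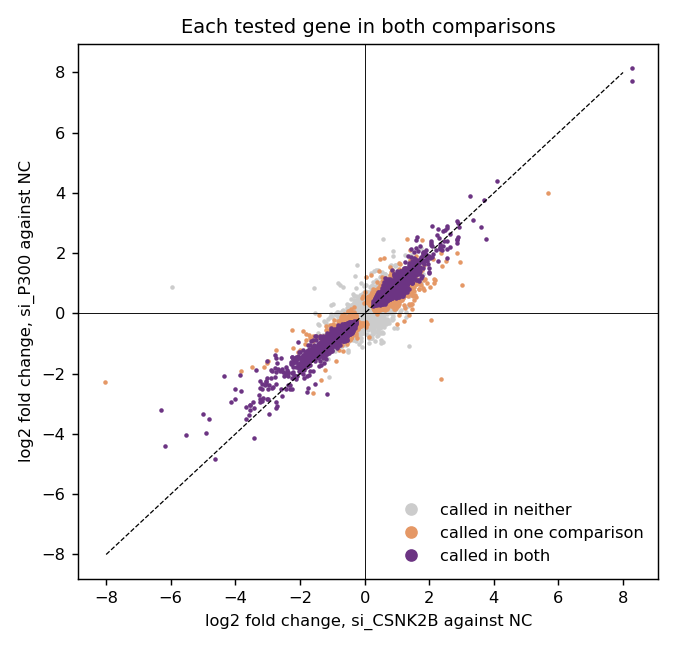
Log2 fold change of each tested gene in si_CSNK2B against NC (horizontal) and in si_P300 against NC (vertical), coloured by whether the gene was called in neither, 1 or both comparisons, with a dashed line where both are equal. The 3194 genes called in both lie in the 2 quadrants of equal sign, and fitted values beyond 8 belong to genes with counts of 0 in all 3 libraries of a group, which depend on the prior count.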

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

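Rounding up, thinning to the shallowest library and leaving out the MTRNR2L genes were added after the data were seen. They gave 4451, 4265 and 4458 genes in si_CSNK2B against NC, 3705, 3536 and 3709 in si_P300 against NC, and 0 in the direct contrast, by edgeR.

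With a log2 fold change of at least 1 the counts were 1078 in si_CSNK2B against NC and 755 in si_P300 against NC, and the overlap was 645. At an adjusted p under 0.01 the counts were 2525 and 1900. Fewer genes can pass a stricter threshold by construction. DESeq2 called 7 genes and limma-trend on log2(TPM + 0.1) without a filter 1 in the direct contrast, where edgeR called 0 (661 at an unadjusted p under 0.05). The log2 fold change of CSNK2B was -0.28 with DESeq2 and passed, while with library sizes alone it was -0.14 and did not (edgeR adjusted p = 0.273). The correlation of both sets of log2 fold changes was 0.946 with the stricter filter and 0.956 over called genes. With an estimated correlation 0 of the 28 list calls passed. Over the 8 lists called in si_CSNK2B against NC it ran from 0.0132 (epithelial-mesenchymal genes) to 0.655 (interferon response), above the preset 0.01. A higher correlation makes the camera p larger, so the p-values at the preset rest on a lower correlation than the data gave. The cause of the other differences was not tested.

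Leaving out 1 library at a time gave 2928 (NC replicate 3) to 4029 genes in si_CSNK2B against NC and 2191 (NC replicate 3) to 3882 in si_P300 against NC, with 2322 without NC replicate 1. The overlap ran from 1942 (NC replicate 3) to 3425, with 2066 without NC replicate 1, the correlation from 0.856 to 0.907, and CSNK2B from -0.34 to -0.20. In the direct contrast the camera direction turned without si_CSNK2B replicate 1 for oxidative phosphorylation (adjusted p = 0.867), and without si_P300 replicate 1 for it (0.980) and for hypoxia and glycolysis (0.181), over ranges of 2.48e-04 to 0.980 and 1.15e-06 to 0.237. The cause was not tested.

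The replicate numbers did not pair the libraries, with correlations of deviations of -0.29 to 0.061 and 0 of 9 highest with their own number. The replicate block gave 3828, 3012 and 0 genes, and 2 list calls were lost (DNA repair in si_P300, camera adjusted p = 0.0536, and oxidative phosphorylation in the direct contrast, 0.0638). By fry 26 list tests passed, 10 of them among the 28 called by camera. Of 259 named results, all of them called in the main fit, 232 kept direction and side of the threshold under every alternative run. Of 3353 values 107 lost the call and 0 reversed. The genes were picked by their size or p in these same libraries, so a high share kept follows in part from the choice.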

Other observations

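The tests of swapped labels, shared controls, control cultures, missing neuroendocrine genes and admixture, and the 3 gene lists of the last paragraph, were chosen after the results were seen. The tests of other splits, depth, GC content and intestinal markers were written before the values they measure were seen, although the thinning that the depth test uses was added after the data were seen.

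Of the 10 splits of the 6 libraries, 1 gave as many as the 4462 genes in si_CSNK2B against NC, and 1 as many as the 3709 in si_P300 against NC, the real split in each, with 0 as the highest other. In the direct contrast 10 of 10 gave at least the real 0, which any count does, and the highest other was 2. Against NC, a mixed split puts the difference between the groups inside its own groups, which lowers its calls. The splits are also too few for a share under 0.05, so no conclusion is drawn from them.

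Both siRNA targets were lower by less than 20% in the libraries labelled with their siRNA, CSNK2B at -16.5% and EP300 at -18.6%, and neither passed. Labels swapped between the knockdown groups would put the lower level of each target in the other group. The log2 difference between si_CSNK2B and si_P300 was -0.0414 for CSNK2B and 0.0258 for EP300, with the interval for CSNK2B at -0.269 to 0.186, which argues against a swap of strongly reduced groups and leaves a swap of groups with a small reduction open. A weak or already ended reduction at 48 hours, or an effect on protein alone, may remain and was not tested, since no protein values were used here.

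Both knockdown groups differed from NC alike, in the stress genes INHBE and TRIB3 and the immediate early genes EGR2 and FOSB among others. Shared controls alone, with noise drawn independently for each gene, are argued against by a covariance 10.4 times the highest simulated one. A shift common to the NC libraries lies outside these simulations. Depth is argued against by 95.6% as many calls at equal depth. GC content and length are argued against by the small size of their fitted trend, a comparison made after the values were seen. Its SD was 0.0608 in si_CSNK2B and 0.0469 in si_P300, against 0.661 and 0.579 for the log2 fold changes of all tested genes. The planned test gave the unfolded protein response and ATF4 list a median of -2.03 in si_CSNK2B once the trend was removed (-1.90 before). So small a trend could hardly have moved that median, and the likeness of both groups was not computed again after removal. The state or day of the NC cultures stays open, because the study has 1 set of controls: a stress response in NC may account for part of the likeness, and it cannot be told apart from a shared effect of both siRNAs.

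The neuroendocrine signature was near 0 in all 9 libraries, although NCI-H69 is a small cell lung cancer line, while FOXA1, FOXA2 and SOX2 of the other neuroendocrine list exceeded 10 CPM in all 9 (33.2, 32.7 and 32.2 CPM in NC). MYCN stood at 0.843 CPM and MYC at 306 CPM in NC, and YAP1, a regulator often absent from neuroendocrine tumours, at 401 CPM. Genes left out of the table are argued against by 80% of the neuroendocrine signature members having a value, and a large share of neuroendocrine cells in a mixture by a highest library median of 0.119 CPM over its 20 measured members, with 0 of them over 10 CPM in all 9 libraries. Intestinal epithelium stays open as a candidate source: 43.8% of its markers exceeded 10 CPM in all 9 libraries (7 of 16, among them CDX2, VIL1, CDH17 and HNF4A), against 25% for hepatocyte, 20% for breast luminal and 8.33% for lung epithelium, a share between the bounds set for and against. The design has no group that would test a biological explanation, and the identity of the cells stays open.

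Another 3 lists are described without a test, since they were assembled after the changes were seen. Aminoacyl-tRNA synthetases, many of them ATF4 targets, had 13 lower and 2 higher of 20 in both comparisons with NC, with medians of -0.90 and -0.76. WARS1 fell by 2.38 and 1.96 on the log2 scale, while RARS1 rose (0.59 and 0.55). EGFR ligands and MAPK feedback genes had 11 lower and 0 higher of 15 in both, with medians of -1.23 and -1.05, including HBEGF (-3.55 and -3.05) and EGFR (-1.93 and -1.87). DUSP4 and DUSP6 of this list are also in the immediate early list. Endoplasmic reticulum chaperones and folding enzymes had 5 higher and 1 lower of 14 in si_CSNK2B and 4 and 1 in si_P300, with HSPA5 at -0.43 and -0.44. Of them CALR, HSP90B1, HSPA5, PDIA4 and SDF2L1 are also in the unfolded protein response and ATF4 list, and CALR and PDIA3 in the MHC class I list. In the direct contrast the medians were -0.15, -0.21 and -0.03 in this order, with 0 members called by edgeR, as for all genes.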
